A study of Mus musculus with 4 samples.

How the data were processed

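Pancreata of wild-type C57BL/6 mice were dissociated, stained with DAPI, and the DAPI-negative cells were sorted and run on the 10x Genomics 3' assay, with 1 library for each of 4 groups: saline or caerulein, and 2 days or 6 weeks of recovery. The deposited matrices held raw counts, as whole UMI numbers per gene and barcode for 31053 genes, in barcodes already called as cells by the authors. The submitters' processing notes name Cell Ranger 3.0.2, FastQC and the mm10 build. Sample groups were taken from the sample titles.

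Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept, which left 3346 (S2D), 4656 (C2D), 2032 (S6W) and 2773 (C6W). Scrublet, run per library within scanpy 1.11.5, called 38, 19, 15 and 32 doublets, and these were left out. In C2D that is 0.408% of cells, a low rate for so many barcodes, so an alternative left out the highest scores at 0.8% per 1000 barcodes (142, 202, 43 and 93 cells). Counts were scaled to 10000 per cell, log-transformed, reduced to 2000 variable genes and 40 principal components, and clustered over 15 neighbours by Leiden at resolution 1, with all libraries together and no integration. Clusters were named from marker lists, with folds taken over the median of all clusters. A name needed a mean log2 marker fold of at least 1 and at least 3 raised markers. A raised marker had a UMI in at least 10% of the cells. The lead over the next class had to be at least 0.5. The 10 leading genes could not hold more markers of another class. Shallow clusters, and those with few raised markers, also needed a marker of their own among these genes. Names mean marker-like, not lineage. Free RNA was gauged from the digestive UMIs of T and B cells (191, 51.3, 115 and 97.2 per cell in S2D, C2D, S6W and C6W) and was not subtracted in the main values.

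UMIs were summed over the cells of a class in each library and scaled by TMM-adjusted totals (edgeR 4.0.16, R 4.3.3). The log2 ratio of caerulein over saline was given with an exact conditional binomial interval at 95%, levels with exact Poisson intervals, and shares of cells with Clopper-Pearson intervals. Cells of 1 library are not replicates, so no p-value was computed. Genes with at least 100 UMIs over both libraries were compared, in classes with at least 50 cells in each, and those with an absolute log2 ratio of 1 or more were counted as at least 2-fold higher or lower. A library without UMIs of a gene was given 3 counts over the group, and such a ratio is a bound. Digestive genes were left out of these counts outside acinar-like cells. Gene list medians used members with at least 20 UMIs and were placed among 10000 random lists matched on level over 20 bins, as a description of these libraries. Intervals of medians came from 1000 Poisson draws.

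Genes were named by a fixed rule: the 10 highest and 10 lowest ratios in acinar-like cells, 5 and 5 in other classes, up to 4 members of each list with the largest ratios, and 15 acinar-like genes whatever their value, leaving out mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed genes. The lists covered digestive enzymes, acinar transcription factors, ductal and metaplasia, progenitor and Notch, AP-1, dissociation, MAPK, Reg, endoplasmic reticulum stress, oxidative stress, cell cycle, interferon, antigen presentation, NF-kB, matrix, quiescent fibroblast, resident macrophage, monocyte and lipid-associated macrophage genes. The comparisons, lists, marker genes, size rule and naming rule were chosen before the data were examined. So were the alternatives of scaling (plain CPM, counts scaled by all UMIs of the class, totals without digestive genes, DESeq2 1.42.0 size factors), count minimum, depth, free RNA, cell filter, doublets kept and clustering. Alternatives chosen after seeing the data were doublets by expected rate, S2D as the control of C6W, leaving out clusters with at least 90% of cells from 1 library, leaving out the shallow and dividing macrophage clusters, and shares among non-immune cells. Genes singled out as markers of other cells (Lyz2, Igkc, Dcn, C1qb, Krt18), and genes named as shared by both times, were chosen after their values were seen. Coordinates came from GENCODE vM21, matched by Ensembl identifier.

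The method was tested on simulated data, with 200 genes changed 2-fold or 4-fold between libraries of the depth of 4 comparisons. Both simulated libraries were drawn from 1 profile, with as many genes raised as lowered. The simulation therefore did not cover a loss of digestive UMIs, on which the signs of acinar-like ratios under each scaling depend. It also held no variation between libraries beyond counting error, so few unchanged genes could pass the size rule. In acinar-like cells at 2 days the median recovered log2 was 1.04 for a simulated 1 and -1.85 for a simulated -2, and 1 of 1573 unchanged genes passed the size rule. In fibroblast-like cells at 6 weeks these were 1.005, -1.98 and 1 of 9772. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.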

Results

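Single-cell RNA was measured in whole mouse pancreas after injury with caerulein, a cholecystokinin analogue that overstimulates acinar cells and causes acute pancreatitis, or after saline. Pancreata were taken after 2 days (saline, S2D; caerulein, C2D) or 6 weeks of recovery (saline, S6W; caerulein, C6W). Each of the 4 groups was 1 library of DAPI-negative sorted cells, so no difference could be tested against variation between animals. All values below are single libraries, and their intervals (exact, 95%) cover counting error only. The libraries held 5316 (S2D), 5433 (C2D), 2623 (S6W) and 4195 (C6W) barcodes, with 36914373, 71547194, 29145886 and 33788935 UMIs in total. After filtering, 3308, 4637, 2017 and 2741 cells were analysed, with a median of 8324, 14051, 10341 and 10541 UMIs per cell. Clustering gave 33 clusters, of which 32 were named by marker genes as 16 classes, and 1 cluster of 56 cells stayed unnamed.

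The first question was how the make-up of the cell suspension differed. Macrophage-like or monocyte-like cells, which clear debris and direct repair, made up 51.5% of C2D cells (50.1 to 53.0%, Clopper-Pearson) and 2.36% of S2D cells (1.87 to 2.93%), a 21.9-fold higher share. Dendritic cells made up 6.90% of C2D (6.19 to 7.67%) and 1.90% of S2D (1.47 to 2.43%). B cells were at 0.367% in C2D (0.214 to 0.586%) against 22.8% in S2D (21.3 to 24.2%), and T cells at 2.22% (1.82 to 2.69%) against 5.53% (4.78 to 6.37%). Ductal-like cells made up 3.80% of C2D (3.26 to 4.39%) and 23.3% of S2D (21.9 to 24.8%). Acinar-like cells, which make the digestive enzymes, were at 16.5% in C2D (15.4 to 17.6%) and 13.03% in S2D (11.9 to 14.2%). Fibroblast-like cells made up 12.7% of C2D (11.7 to 13.7%) and 20.7% of S2D (19.4 to 22.2%), but 35.1 and 35.0% of the non-immune cells, a denominator chosen after the data were seen. Under it the ratio of C2D to S2D shares was 0.2678 for ductal-like cells (0.1631 of all cells) and 2.077 for acinar-like cells (1.265 of all cells).

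After 6 weeks, macrophage-like cells were at 4.12% in C6W (3.41 to 4.94%) and 6.45% in S6W (5.41 to 7.61%). Ductal-like cells made up 20.2% of C6W (18.7 to 21.7%) and 10.9% of S6W (9.53 to 12.3%), while acinar-like cells made up 13.2% (upper bound 14.6%) and 22.3% (20.5 to 24.2%). Blood endothelial cells were at 0.547% in C6W (0.307 to 0.901%) against 6.94% in S6W (5.87 to 8.14%). The saline libraries also differed: B cells were at 22.8% in S2D and 6.15% in S6W (5.14 to 7.29%), and blood endothelial cells at 1.45% in S2D (1.07 to 1.92%). With S2D as the control, the share ratios of C6W were 1.749 for macrophage-like, 0.8668 for ductal-like, 1.016 for acinar-like and 0.3771 for blood endothelial cells, against 0.6397, 1.858, 0.5935 and 0.07884 with S6W. Dissociation and the DAPI sort can set such shares, which was not tested.

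**Figure D1:**
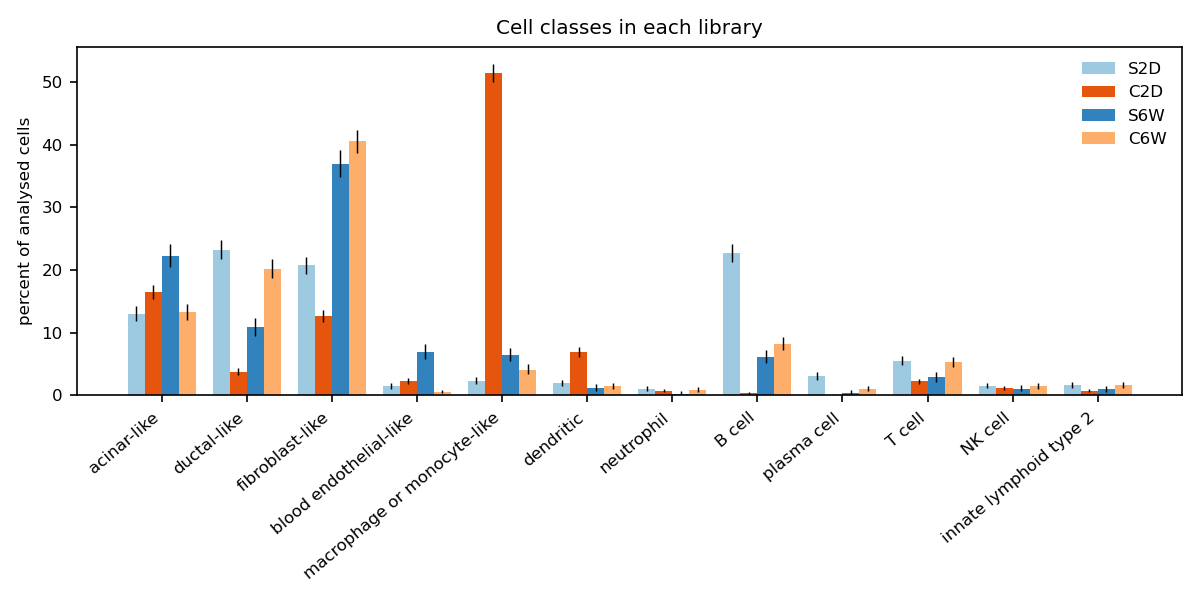
Percent of analysed cells in each class (vertical axis) for the 4 libraries, with exact 95% binomial intervals as bars. Macrophage-like cells stand at 51.5% in C2D and between 2.36 and 6.45% in the other libraries.

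Within classes, the acute response was read first in acinar-like cells, of which C2D gave 764 and S2D 431. Their median mitochondrial share was 0.22% in S2D, 0.03% in C2D, 0.17% in S6W and 0.28% in C6W, against 2.83 to 3.37% in fibroblast-like cells. They had a median of 447 genes in S2D, 1194.5 in C2D, 518.5 in S6W and 536 in C6W. Whether these barcodes held intact cells was not tested. Digestive enzyme genes were lower in C2D: 34 of 38 measured members were at least 2-fold lower, with a median log2 ratio of -3.88 (-1.43 under plain CPM). Plain CPM raised every ratio of these cells by the same amount, so the size of this fall depends on the scaling. Digestive genes had a mean of 5476 UMIs per acinar-like cell in C2D and 11010 in S2D. Pnlip, pancreatic lipase, stood at -6.69 (-6.71 to -6.68), Cela1, an elastase, at -5.85 (-5.86 to -5.84), Cpa1, a carboxypeptidase, at -3.94 (-3.95 to -3.93) and Prss2, a trypsinogen whose copies share reads, at -3.13 (-3.14 to -3.13). Digestive genes took a median of 45.7% of the UMIs of a C2D acinar-like cell and 86.4% in S2D. Of 13 acinar transcription factors 4 were at least 2-fold lower and 1 higher (median -0.76, but 1.69 under plain CPM, which scales by all UMIs of the class), with Bhlha15, which drives secretory maturation, at -2.29 (-2.58 to -2.00; 0.16 under plain CPM), Rbpjl at -1.57 (-1.75 to -1.39; 0.87) and Ptf1a at -0.64 (-1.01 to -0.26). Endoplasmic reticulum stress and folding genes were lower in 18 of 22 (median -1.94, but 0.51 under plain CPM), among them Derl3 at -4.53 (-4.89 to -4.19) and Herpud1 at -3.04 (-3.18 to -2.91).

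Genes of ductal cells and of acinar-to-ductal metaplasia were higher in the same cells: 15 of 27 were at least 2-fold higher and 4 lower, with a median of 1.34. Krt19, a duct keratin, was 8.13-fold higher (log2 3.02, 2.56 to 3.53), and Cldn4, a tight junction claudin, stood at 5.08 (4.10 to 6.29), Krt7 at 4.84 (2.98 to 7.89) and Anxa3 at 5.94 (3.46 to 11.25). Sox9, a duct transcription factor, was at -1.09 (-1.62 to -0.52) and Spp1, osteopontin, at -1.03 (-1.30 to -0.75), although plain CPM gave 1.36 and 1.42. Reg genes, secreted in acute pancreatic injury, had a list median of 0.82, with Reg3b 18.9-fold higher (log2 4.24, 4.14 to 4.35) and Reg3g at 3.59 (3.32 to 3.87), and Clu, a secreted chaperone, stood at 1.46 (1.41 to 1.51). Cell cycle genes were at least 2-fold higher in 10 of 15 (median 1.32; Stmn1 4.87, 3.32 to 7.15), MAPK output genes in 8 of 15 (median 1.01; Hbegf 2.21, 1.42 to 3.12) and oxidative stress genes in 7 of 14 (median 0.90; Gpx2 4.61, 2.75 to 7.66). Among the 10 genes with the highest ratios were also Tspan1 at 6.41 (3.93 to 11.72), Plin2 and Pmm1, and Lgals3 and Sprr1a, which had no S2D UMI and were at least 46.2-fold and 39.4-fold higher.

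In all, 929 of 5107 genes were at least 2-fold higher and 701 at least 2-fold lower in C2D. Because digestive mRNA fills most of an S2D cell, plain CPM put the median of all genes at 2.54 and gave 4713 higher and 50 lower, totals without digestive genes put it at 0.46 and gave 1474 and 444, and TMM put it at 0.09. The acinar-like cells of C2D lay in clusters 27 and 31 (56.2 and 43.8%) and those of S2D in cluster 5 (99.3%), so a cluster may be its library rather than a type. RNA of other cells moved with these genes: Lyz2, of macrophages, was at 108.3 CPM in C2D and 1.64 in S2D, and Igkc, of plasma and B cells, at 5.01 and 187.1, so that the lowest ratios were those of immunoglobulin genes (Ighg3, Iglc2, Igkc, Ighm). The other lists had medians of -0.23 (AP-1 factors, with Jun at -1.25 and 1.19 under plain CPM), -0.10 (dissociation genes), 0.24 (progenitor and Notch genes), 0.20 (NF-kB and cytokine genes), -0.48 (interferon response), -0.65 (antigen presentation), -0.32 (matrix), -1.85 (quiescent fibroblast), 0.72 (resident macrophage), 0.05 (monocyte) and -0.01 (lipid-associated macrophage), and plain CPM made all of them positive, as totals without digestive genes did for the AP-1, dissociation, matrix and lipid lists.

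Macrophage-like cells of C2D (2389, against 78 in S2D) carried a lipid-handling programme: 11 of 15 lipid-associated macrophage genes were at least 2-fold higher, with a median of 2.19 (1.44 with cells thinned to 1000 UMIs). Gpnmb, a glycoprotein of phagocytic macrophages, stood at 5.64 (4.52 to 7.08), Fabp5, a fatty acid binding protein, at 4.46 (3.97 to 4.999), Ctsd, a lysosomal protease, at 4.29 (4.11 to 4.48) and Spp1 at 3.78 (3.47 to 4.11). Thbs1, thrombospondin, was at 5.18 (4.46 to 6.02), Syngr1 at 6.00 (4.45 to 8.27) and Arg1, arginase, at 3.98 (2.13 to 7.03) from 2 UMIs in S2D. With cells thinned to 1000 UMIs Arg1 was at -0.11. With so few S2D UMIs that value can be a bound set by the floor of 3 counts, so it cannot decide the direction. Antigen presentation genes were lower in 8 of 13 (median -1.57; H2-Eb1 -2.94, -2.97 to -2.90; H2-Aa -2.74, -2.77 to -2.70) and interferon response genes in 11 of 20 (median -1.03; Ifit2 -4.12, -4.49 to -3.75; Ifit1 -2.55, -2.78 to -2.32). RNA of other cells moved here too, with Igkc at 568.5 CPM in S2D and 6.35 in C2D. Resident macrophage genes had a median of -0.15, monocyte genes 0.17 (-0.88 with cells of 1000 UMIs or more) and dissociation genes -0.62. Over 9282 genes, 1195 were at least 2-fold higher and 698 lower. For this class S2D held 678932 UMIs and C2D 34039100, so genes near the minimum of 100 UMIs rest on few S2D UMIs. At a minimum of 400 UMIs, which compares fewer genes, 743 were higher and 269 lower. Of the C2D cells 73.7% lay in cluster 29, which held 2 S2D cells, and 73.1% of the S2D cells lay in cluster 3.

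Fibroblast-like cells of C2D (587, against 686) had higher levels of matrix and myofibroblast genes, 20 of 26 of them by at least 2-fold and none lower, with a median of 2.09. Cthrc1, a secreted regulator of collagen deposition, stood at 7.35 (6.54 to 8.31), Thbs4 at 7.77 (7.07 to 8.58), Postn, periostin, at 5.50 (5.34 to 5.67), Col8a1 at 4.84 (4.47 to 5.24) and Tagln, a smooth muscle actin-binding protein, at 4.78 (4.46 to 5.11). Quiescent fibroblast genes were lower in 9 of 16 (median -1.59), with Gsn at -3.39 (-3.41 to -3.38), Efemp1 at -2.98 (-3.07 to -2.88) and Clec3b at -2.43 (-2.48 to -2.39). Cell cycle genes were at least 2-fold higher in 12 of 22 (median 1.48; Cdk1 5.45, 3.57 to 8.51), and dissociation genes had a median of -0.12. Over 9897 genes, 907 were at least 2-fold higher and 582 lower, or 757 and 745 with totals without digestive genes. C1qb, a macrophage gene, was at 103.8 CPM in these C2D cells and 0.54 in S2D, and 92.0% of them lay in cluster 24, which held 6 S2D cells.

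Ductal-like cells of C2D (176, against 770) showed cell cycle genes at least 2-fold higher in 25 of 27, with a median of 4.98 that was 1.78 at a minimum of 400 UMIs and 1.46 with cells thinned to 1000 UMIs, among them Cenpf at 7.30 (5.93 to 9.18), Ccnb2, cyclin B2, at 8.65 (6.16 to 13.96) and Tpx2, a spindle factor, at 8.03 (5.53 to 13.34). Lcn2, an iron-sequestering defence protein, was 28.6-fold higher (log2 4.84, 4.76 to 4.92), C3, complement, stood at 4.40 (4.23 to 4.57) and Il1rn, the interleukin 1 receptor antagonist, at 7.93 (7.01 to 9.07). NF-kB and cytokine genes were at least 2-fold higher in 9 of 19 (median 0.76), with Cxcl5, a neutrophil attractant without a UMI in S2D, at least 94.7-fold higher. Ductal and metaplasia genes had 9 of 26 higher and 2 lower (median 0.58; Cd44 2.24, 2.05 to 2.42), and interferon response genes 2 higher and 7 lower of 17 (median -0.67). Over 9012 genes, 482 were at least 2-fold higher and 445 lower, or 388 and 632 under plain CPM, whose median was -0.12. Dissociation genes had a median of -0.06 and Lyz2 stood at 276.7 CPM against 2.29, and 90.3% of the C2D cells lay in cluster 20, which held 3 S2D cells.

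**Figure D2:**
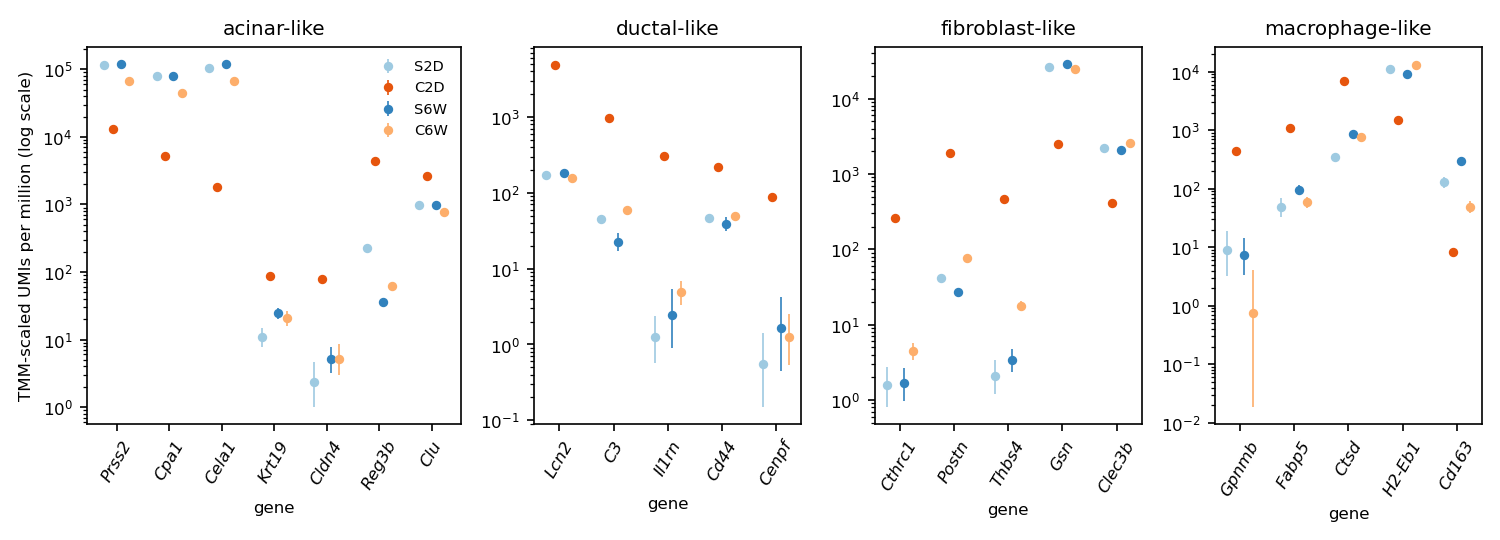
Level of named genes in 4 cell classes (CPM of TMM-adjusted totals, log scale) in the 4 libraries, as points with exact 95% Poisson intervals. C2D stands apart, with Prss2, Cpa1 and Cela1 lower and Krt19 and Reg3b higher in acinar-like cells, and with plain CPM the sign stays the same for these 5 genes.

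The second question, which the title of the series names as a memory of inflammation, was what was left after 6 weeks. In acinar-like cells (363 in C6W, 450 in S6W) differences were small: 35 of 1479 genes were at least 2-fold higher and 17 lower, beside 12 and 26 of 1559 between the saline libraries. Plain CPM gave 101 and 4, with a median of all genes of 0.32 against -0.19 under TMM. Digestive enzyme genes had a median of -0.66, with 5 of 38 at least 2-fold lower and none higher, and plain CPM gave -0.15. Cel, a bile salt lipase, stood at -1.26 (-1.28 to -1.24), Amy2a5, an amylase whose copies share reads, at -1.08 (-1.17 to -0.99), Prss2 at -0.83 (-0.83 to -0.82) and Cpa1 at -0.87 (-0.88 to -0.86). Against S2D they stood at -0.98, -1.08, -0.77 and -0.83. Sdf2l1, an endoplasmic reticulum chaperone, was at -1.10 (-1.35 to -0.85), and its list had a median of -0.44, or 0.07 under plain CPM.

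The genes with the highest 6-week ratios in acinar-like cells were Ccnl1 at 2.11 (1.46 to 2.80), Chka, choline kinase, at 1.89 (1.51 to 2.27), Son, Ighm, Neat1 and H2-Ab1. Against S2D, however, Ccnl1 stood at 0.48, Chka at 1.06, Son at 0.61 and Neat1 at 0.10. Spp1 was at 1.66 (1.30 to 2.03) and Cxcl1, a neutrophil attractant, at 1.66 (1.16 to 2.17), and against S2D at 0.77 and 1.14. H2-Ab1 stood at 1.70 (1.10 to 2.32), Ighm at 1.81 (1.44 to 2.19) and Klf2 at 1.503 (0.93 to 2.10), but against S2D at -0.07, -0.04 and -0.26. NF-kB and cytokine genes had a median of 1.07, ductal and metaplasia genes 0.19 (-0.16 at a minimum of 400 UMIs), AP-1 factors 0.33 (-0.05 against S2D), Reg genes 0.22 (-0.69 against S2D) and acinar transcription factors -0.23, or 0.28 under plain CPM. MAPK output genes were at 0.30, oxidative stress genes at -0.20 (0.31 under plain CPM), antigen presentation genes at 1.09 (-0.23 against S2D), matrix genes at 1.09 and quiescent fibroblast genes at 1.07 (-0.71 and -0.30 with doublets by expected rate), monocyte genes at 1.78 and lipid-associated macrophage genes at 0.15 (-0.20 with cells thinned to 1000 UMIs). Krt19 was at -0.24 (-0.70 to 0.22), Sox9 at 1.003 (0.22 to 1.81), Reg3b at 0.80 (0.49 to 1.11) and Ptf1a at 0.40 (-0.06 to 0.86). Against S2D these 4 stood at 0.95, 0.11, -1.88 and 0.31. RNA of other cells and dissociation genes moved too: Dcn, of fibroblasts, was at 61.9 CPM in C6W and 20.9 in S6W, Igkc at 117.9 and 29.9, and dissociation genes had a median of 0.62.

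The genes that differed at 2 days kept a small lean. Those at least 2-fold higher had a median of 0.07 at 6 weeks (540 genes measured; 0.01 to 0.12 by Poisson draws), above 99.98% of random lists matched on level, whose range was -0.11 to 0.01. Those lower had a median of -0.21 (699 genes), below all but 0.10% of random lists, whose range was -0.19 to -0.12. They lay inside the random range at a minimum of 20 UMIs (-0.151, range -0.156 to -0.09), at 400 UMIs (-0.272, range -0.276 to -0.172) and with cells thinned to 1000 UMIs (-0.107, range -0.124 to 0.026). Among the 1469 genes compared at both times, 4 were at least 2-fold higher and 10 at least 2-fold lower at both, where independence gave 2.04 and 3.89. By contrast, 1 was higher at 2 days and lower at 6 weeks and 11 the other way, against 0.779 and 10.2. The 10 were Amy1, Amy2a2, Amy2a3, Amy2a5, Cel, Cpn1, Cryab, Fxyd1, Pld3 and Sdf2l1. The lean of the higher genes was lost when clustering left out the digestive genes (-0.005) and when doublets were kept (0.006, range -0.09 to 0.02), and was 0.43 under plain CPM, at percentile 54.95.

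Fibroblast-like cells also kept a small lean. Their 2-day higher genes had a median of 0.11 (857 genes) and their 2-day lower genes -0.07 (582 genes), outside the random ranges of -0.02 to 0.02 and -0.02 to 0.03. Under plain CPM they were 0.02 and -0.155, against random ranges of -0.13 to -0.09 and -0.125 to -0.085. The lean of the lower genes was not kept at a minimum of 400 UMIs (-0.006) or with cells thinned to 1000 UMIs (0.12, 157 genes). In ductal-like cells the 2-day genes lay inside the random ranges in the main values, the higher at 0.032 (-0.027 to 0.035) and the lower at -0.014 (-0.032 to 0.016). The higher genes lay above theirs under plain CPM (0.081, range -0.022 to 0.048), totals without digestive genes (0.082) and doublets by expected rate (0.063). They also did with cells of 1000 UMIs or more (0.043) and clustering without digestive genes (0.038), and stayed inside under the other alternatives. With cells thinned to 1000 UMIs the lower genes were at 0.102, above their range of -0.098 to 0.043. In T cells the 80 higher genes lay inside theirs, at 0.035. The 44 lower genes of T cells lay at 0.181, above theirs (-0.154 to 0.116). The lower genes of T cells lay inside it with doublets kept (-0.04) and with Leiden resolution 2 or clustering without digestive genes (-0.078 in each). At a minimum of 20 UMIs they lay below it (-0.068, range -0.065 to 0.115). In fibroblast-like cells at both times 26 genes were at least 2-fold higher and 24 lower, where independence gave 3.52 and 3.46. By contrast, 9 were higher at 2 days and lower at 6 weeks and 4 the other way, against 4.02 and 3.03. At 6 weeks Postn stood at 1.51 (1.32 to 1.71), Tnc, tenascin C, at 1.59 (1.22 to 1.98) and Timp1, an inhibitor of matrix proteases, at 1.12 (0.98 to 1.26), and against S2D at 0.90, 1.198 and 1.49. Thbs4 was at 2.39 (1.87 to 2.94), but at -0.10 without cluster 24, which held 22 C6W and 10 S6W cells. Saa3 was at 3.73 (2.64 to 5.08), Has1, hyaluronan synthase, at 1.30 (1.25 to 1.35) and Dlk1 at -2.77 (-2.95 to -2.59; -1.79 against S2D), while matrix genes had a median of 0.14 and dissociation genes 0.24. Over 9886 genes, 60 were at least 2-fold higher and 70 lower, or 38 and 96 under plain CPM with a median of -0.11, beside 53 and 49 of 9432 between the saline libraries.

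Macrophage-like cells (113 in C6W, 130 in S6W) had lower resident macrophage genes, 12 of 16 by at least 2-fold (median -1.70): Lyve1 at -3.44 (-3.92 to -3.00), Cd163, a haemoglobin scavenger receptor, at -2.62 (-3.02 to -2.23) and Cbr2 at -2.43 (-2.75 to -2.13). The S6W library stood apart here, and against S2D the same 3 genes were at -0.88, -1.38 and -0.82. RNA of other cells also moved: Krt18, of ductal-like cells, was at 99.6 CPM in C6W and 11.6 in S6W. Monocyte genes had a median of 0.83, with Ccr2, the receptor that brings monocytes into tissue, at 1.40 (1.09 to 1.73; 0.67 against S2D) and Plac8 at 1.71 (1.06 to 2.41), though Plac8 was at -1.45 against S2D. NF-kB and cytokine genes had a median of -0.64 and 0.16 against S2D, and dissociation genes -0.25. Over 2929 genes, 94 were at least 2-fold higher and 175 lower, or 44 and 24 of 2383 against S2D and 50 and 97 without the shallow and dividing clusters. The 2-day higher genes of macrophage-like cells had a median of -0.15 at 6 weeks and the lower genes 0.18, opposite in sign to 2 days, with random ranges of -0.06 to 0.05 and -0.07 to 0.05. Without the shallow and dividing clusters the lower genes were at -0.02. With cells thinned to 1000 UMIs they were at -0.24 and the higher genes inside their random range (-0.127, range -0.211 to 0.027).

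Interferon response genes had positive medians for C6W over S6W in ductal-like, fibroblast-like, macrophage-like, B and T cells. In ductal-like cells (553 and 219) 7 of 17 were at least 2-fold higher and none lower (median 0.91, 0.77 to 1.31 by Poisson draws), with Ifit1, an antiviral effector, at 2.93 (1.97 to 4.08; 0.45 against S2D) and Isg15 at 0.98 (0.66 to 1.31; 0.61 against S2D). In fibroblast-like cells 6 of 18 were at least 2-fold higher (median 0.72, 0.67 to 0.80), and the medians were 0.73 in B cells (0.08 to 0.85) and 0.39 in T cells, where the interval of -0.06 to 0.61 held 0. Macrophage-like cells had 4 of 17 higher and 2 lower (median 0.27, 0.05 to 0.43), with Ifit1 at -1.09 and Isg15 at -0.46. That median was -0.259 at a minimum of 400 UMIs and -0.127 with cells thinned to 1000 UMIs. Against S2D the medians were 0.61 (ductal), 0.32 (fibroblast), -0.26 (B), -0.14 (T) and -0.22 (macrophage). Ductal-like cells differed least, with 23 of 8186 genes at least 2-fold higher and 8 lower, beside 26 and 41 of 8512 between the saline libraries. The 23 included Ccl5, a T cell chemokine, at 6.21 (3.72 to 11.52) from 1 UMI in S6W, and Meg3 at 3.15 (2.35 to 4.07; 1.22 against S2D), while dissociation genes had a median of 0.21. Meg3 was also a leading gene of fibroblast-like cluster 6, and Dcn stood in these ductal-like cells at 24.64 CPM in C6W and 13.95 in S6W.

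**Figure D3:**
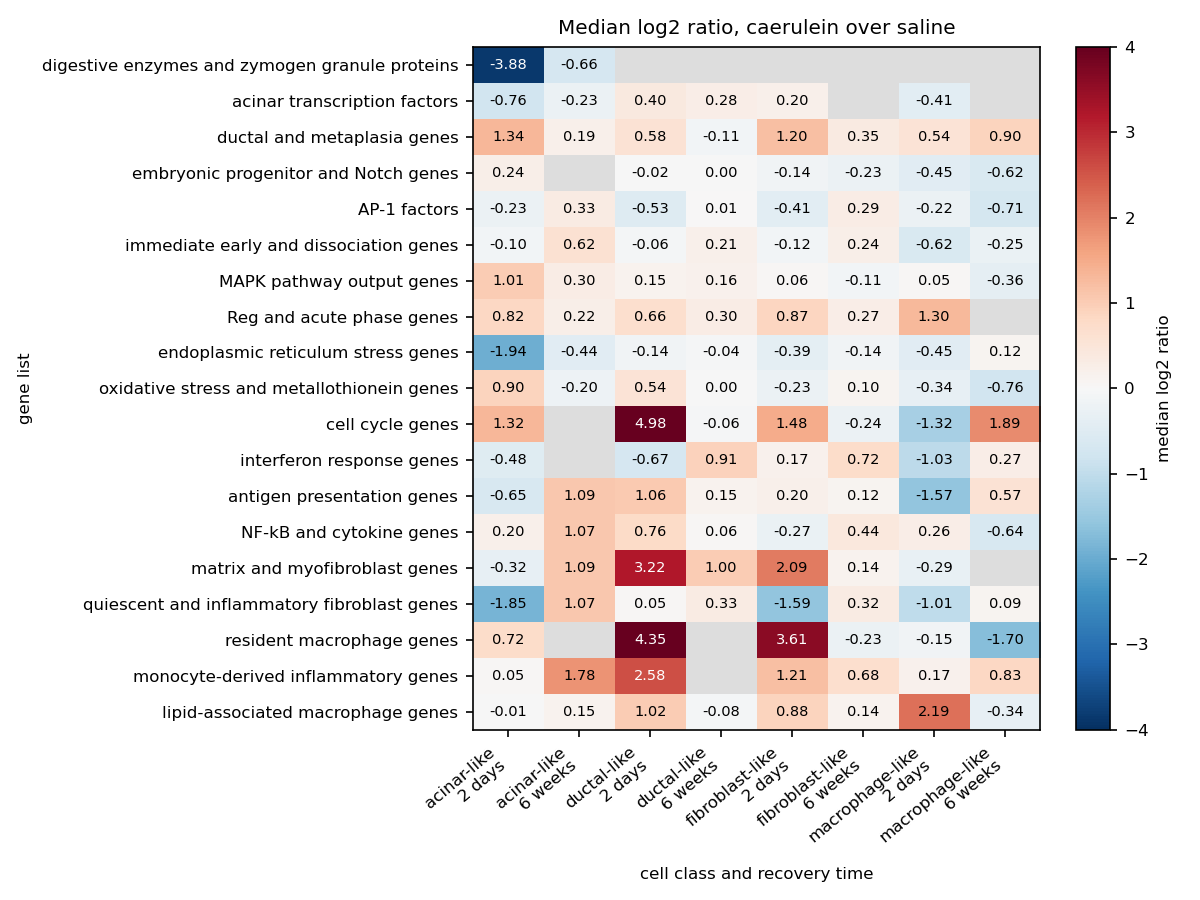
Median log2 ratio of caerulein over saline for each gene list (rows) in 4 classes at both times (columns), under TMM scaling, with lists of fewer than 5 measured members in grey and digestive genes scored in acinar-like cells only. The 2-day values run from -3.88 to 4.98, and under plain CPM the negative 2-day medians of acinar-like cells turn positive except that of digestive genes, -1.43, as do those of acinar transcription factors, endoplasmic reticulum stress and oxidative stress at 6 weeks, while in other classes only medians close to 0 turn.

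The main genes lie, in the mm10 assembly, on chromosome 6 at 41521787 to 41525079 (Prss2, ENSMUSG00000057163), chromosome 19 at 58652498 to 58681788 (Pnlip, ENSMUSG00000046008), chromosome 11 at 100140810 to 100148665 (Krt19, ENSMUSG00000020911), chromosome 6 at 78370657 to 78373466 (Reg3b, ENSMUSG00000071356), chromosome 3 at 54361109 to 54391037 (Postn, ENSMUSG00000027750) and chromosome 6 at 49036546 to 49070929 (Gpnmb, ENSMUSG00000029816). All are annotated as protein coding.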

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

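The tests of the spread of other pairs of libraries, of marker share, of free RNA beyond matched lists, of S2D as the control and of dissociation genes beside interferon genes were chosen only after the results were seen, and the other tests of this part were chosen before.

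In acinar-like cells 929 genes were at least 2-fold higher in C2D. Loss of digestive UMIs from the total, which raises every other gene by 1 factor, cannot be told apart. Under totals without digestive genes 100% of the 929 genes stayed at least 2-fold higher, but that scaling raises every ratio. Of 4326 other genes 13.43% lay at least 2-fold above their median ratio at 2 days, beside 7.03% for C6W over S6W. The bound against this cause asked for 2 times the percent of each pair of libraries without C2D, and was not met there. It was met for the other pairs, with 12.28% beside 2.775% (S6W over S2D) and 12.08% beside 4.508% (C6W over S2D). For free RNA or doublets from macrophage-like cells and fibroblast-like cells, the test chosen beforehand came out in favour: 75.67% of the genes stood higher in one of those classes of C2D. The share of their RNA that their own markers allow argued against it as the whole cause: it gave at least 50% of the level for 2.045% of the genes at the median marker, 2.476% at the upper quartile and 3.122% at the highest. Depth per cell stays open and cannot be told apart, since 63.48% of the 356 genes still measurable after thinning stayed at least 2-fold higher. Thinning also leaves fewer UMIs per gene, so it cannot separate depth from counting error. Mean total depth was close, at 13070 UMIs per acinar-like cell in C2D and 12760 in S2D, though the medians were 8926 and 6475. Outside digestive genes the mean was not close, at 7593 UMIs per cell in C2D and 1752 in S2D. A response of acinar cells to caerulein may remain beside depth.

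In acinar-like cells the genes higher at 2 days lay at 0.07 at 6 weeks and the lower genes at -0.21, where random lists matched on level ranged from -0.11 to 0.01 and from -0.19 to -0.12. The dissociation list stood at 0.615, which is what dissociation stress needs for the higher genes. For the lower genes this opposite sign met the bound set beforehand against such stress. But the list holds only genes taken to rise with dissociation, so it cannot decide for genes that fall. Free RNA cannot be told apart: the lower genes stood at -0.035 in the nearer of T and B cells and so met the bound set beforehand against it, but that bound took the whole -0.21, most of which matched lists shared, and the higher genes stood at 0.045 in T cells and -0.04 in B cells. Of the distance from matched lists in acinar-like cells, T cells showed 36.35% for the higher genes (3.70 to 89.3% by resampling genes) and B cells 40.12% for the lower genes (-64.0 to 176.2%). A lasting acinar difference may stay among the open explanations, and no test of it against animals was possible with 1 library per group.

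Interferon response genes had higher medians in C6W than S6W in ductal-like cells, fibroblast-like cells, B cells and T cells, though the T cell interval of -0.06 to 0.61 held 0, and macrophage-like cells had 0.27. Dissociation stress was argued against, since the highest dissociation median among these classes was 0.244. A low S6W library may account for the pattern in fibroblast-like cells, B cells and T cells, whose medians against S2D were 0.319, -0.255 and -0.138. In ductal-like cells the median against S2D was 0.608, which is 66.5% of that against S6W, so a low S6W library and a caerulein difference cannot be told apart there. The same ductal list had stood at -0.668 at 2 days and 0.914 at 6 weeks, of opposite sign, and the difference was not tested.

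The following values had opposite directions at 2 days and 6 weeks, and the difference was not tested for any of them. Quiescent fibroblast genes in acinar-like cells had medians of -1.852 and 1.074, though 0.596 at 2 days under plain CPM, and Dcn, of fibroblasts, stood in these cells at 64.7 CPM in S2D, 9.72 in C2D, 20.9 in S6W and 61.9 in C6W. Cell cycle genes in macrophage-like cells had medians of -1.317 and 1.892, but -0.315 and 0.302 without the shallow and dividing clusters, and 0.578 at 6 weeks against S2D. Antigen presentation genes in macrophage-like cells had medians of -1.565 and 0.567. The ratio of the acinar share, caerulein over saline, was 1.265 and 0.5935, and that of the ductal share 0.1631 and 1.858. The macrophage share ratio was 21.85 and 0.6397, and the T cell share ratio 0.4015 and 1.839. With S2D as the control of C6W the 6-week ratios of these 4 classes were 1.016, 0.8668, 1.749 and 0.9563, on the same side of 1 as at 2 days, though the acinar (0.844 to 1.224) and T cell (0.704 to 1.297) intervals held 1. The 2-day ratios share that S2D library as their control, so lying on the same side is partly built in. Barcodes with over 20% mitochondrial UMIs were left out of the comparisons. They made up 33.59% of all deposited C6W barcodes (32.16 to 35.04%), against 11.4% in S6W (10.24 to 12.72%), while S2D had 36.6% and C2D 13.01%.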

How the results depend on the processing

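S2D as the control, doublets by expected rate, leaving out clusters of 1 library, leaving out shallow and dividing macrophage clusters, and the non-immune denominator were alternatives chosen after seeing the data. No paired analysis was possible because each group was 1 library. Over all alternatives, 181 of 256 counts stayed within 1.5 times, 1244 of 1606 ratios of 137 genes stayed within their interval while 15 turned direction, and 662 of 849 medians of 69 lists stayed while 19 turned. These turns cover genes past 2-fold and lists outside their random range, and with the smaller values 37 gene ratios and 62 list medians changed sign. Of 105 share ratios 94 stayed and 5 turned. Lists have no value under the 20 UMI minimum, which is already theirs. Except where the construction is named, the cause was not tested.

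Among non-immune cells only, 2-day share ratios were 2.077 for acinar-like (1.265 in the main values), 0.2678 for ductal-like (0.1631), 1.003 for fibroblast-like (0.6104, reversed) and 2.564 for blood endothelial cells (1.56), since immune cells leave the denominator.

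Plain CPM, which counts digestive UMIs in the total, gave 4713 higher and 50 lower acinar genes at 2 days, 101 and 4 at 6 weeks, and 38 higher fibroblast genes at 6 weeks. The 2-day genes at 6 weeks were at 0.426 and -0.020 (acinar higher and lower), -0.134 (macrophage higher), 0.019 and -0.155 (fibroblast). Digestive genes were at -1.427 and fibroblast matrix genes at 1.998. In acinar-like cells at 2 days it reversed transcription factors (1.69), endoplasmic reticulum stress (0.509) and quiescent fibroblast genes (0.596), Bhlha15 (0.155), Rbpjl (0.874), Sox9 (1.359), Spp1 (1.422) and Jun (1.19), and at 6 weeks endoplasmic reticulum stress genes (0.072). Inside their random ranges it also changed the sign of the AP-1 (2.22), dissociation (2.352), interferon (1.964), antigen presentation (1.794), matrix (2.129) and lipid lists (2.443) at 2 days, and of transcription factors (0.282) and oxidative stress genes (0.313) at 6 weeks. Totals without digestive genes gave 1474 and 444 acinar genes at 2 days, 7 lower at 6 weeks, 37 higher fibroblast genes at 6 weeks and 668 lower ductal genes at 2 days. The 2-day genes were at 0.187 and -0.079 (acinar), -0.139 (macrophage higher), 0.018 and -0.154 (fibroblast), digestive genes at -3.508 and matrix genes at 1.976. DESeq2 size factors moved the macrophage higher genes to -0.137, free RNA subtraction to -0.151 and Leiden resolution 2 to -0.288.

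A minimum of 20 UMIs compares more genes by construction. It gave 1833 and 1429 acinar genes (higher and lower) at 2 days, 336 and 270 at 6 weeks, and 219 and 240 between saline libraries. Macrophage counts were 2206 lower at 2 days and 469 and 546 at 6 weeks. The 2206 can hold genes without a S2D UMI that pass as lower only through the floor of 3 counts. For this class S2D held 678932 UMIs and C2D 34039100, and the higher genes stayed at 1195. Fibroblast counts were 1506 and 1083, then 235 and 217, and ductal counts 1071 and 935, then 266 and 91. The acinar 2-day lower genes were at -0.151.

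A minimum of 400 UMIs compares fewer genes by construction. It gave 268 and 279 acinar genes at 2 days, 4 and 9 at 6 weeks, and 9 lower between saline libraries. Macrophage counts were 743 and 269, then 16 and 57, fibroblast counts 521 and 303, then 22 and 28, and ductal counts 181 and 165, then 3 and 1. The 2-day lower genes were at -0.272 (acinar), 0.111 (macrophage) and -0.006 (fibroblast). Acinar ductal and metaplasia genes at 6 weeks reversed to -0.156, fibroblast matrix genes were at 2.002 and ductal cell cycle genes at 1.779.

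Thinning to 1000 UMIs per cell leaves fewer UMIs by construction. It gave 134 and 97 acinar genes at 2 days, 3 and 2 at 6 weeks, and 5 and 6 between saline libraries. Macrophage counts were 601 and 146, then 3 and 20, fibroblast counts 176 and 157, then 15 and 7, and ductal counts 79 and 101, then 4 and 1. The 2-day genes were at 0.139 and -0.107 (acinar), -0.127 and -0.237 (macrophage, the latter reversed), 0.159 and 0.121 (fibroblast, the latter reversed). Digestive genes were at -3.154, macrophage lipid genes at 1.439, ductal cell cycle genes at 1.459, and reversed were acinar AP-1 factors (-0.002) and lipid genes (-0.197) at 6 weeks and macrophage Arg1 at 2 days (-0.108). The Arg1 value can be a bound set by the floor of 3 counts, since few S2D UMIs were there to thin.

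With S2D as control, 6-week share ratios reversed for acinar-like (1.016), ductal-like (0.8668), macrophage-like (1.749) and T cells (0.9563), and were 1.956 for fibroblast-like, 0.3639 for B and 0.3771 for blood endothelial cells (1.097, 1.347 and 0.07884 in the main values). At 6 weeks there were 15 higher acinar genes, 44 and 24 macrophage genes and 23 lower ductal genes. Reversed were antigen presentation (-0.230), AP-1 (-0.053) and Reg genes (-0.691) in acinar-like cells, NF-kB genes in macrophage-like cells (0.159), dissociation genes in fibroblast-like cells (-0.125), interferon genes in B (-0.255) and T cells (-0.138), acinar Ighm (-0.042), H2-Ab1 (-0.069), Igkc (-1.076) and Klf2 (-0.259), macrophage Plac8 (-1.451) and Cxcl1 (0.199), and ductal Cxcl2 (-1.037). Smaller values that changed sign included acinar Reg3b (-1.883), Krt19 (0.947) and Nr5a2 (0.478) and macrophage interferon genes (-0.219).

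Doublets by expected rate reversed acinar matrix (-0.714), quiescent fibroblast (-0.296) and lipid genes (-0.135) at 6 weeks, and gave 23 higher acinar genes, 30 and 16 genes between saline libraries, digestive genes at -4.005 and fibroblast Cxcl13 at 6 weeks at 0.042 (-3.914 in the main values, reversed). Doublets kept gave 24 higher genes between saline libraries, 37 and 13 ductal genes at 6 weeks, acinar 2-day higher genes at 0.006, inside their random range, digestive genes at -3.709, and acinar lipid genes at 6 weeks at -0.247 (reversed). Clustering without digestive genes gave 22 higher genes between saline libraries, digestive genes at -3.663 and reversed acinar lipid genes at 6 weeks (-0.204) and the acinar 2-day higher genes (-0.005). Without the shallow and dividing clusters, macrophage counts at 6 weeks were 50 and 97, and the 2-day genes were at -0.100 and -0.021 (the latter reversed). Without clusters of 1 library the acinar 2-day genes were at 0.192 and -0.175, and fibroblast Thbs4 at 6 weeks reversed to -0.104.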

Other observations

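The test of acinar origin was chosen only after the ductal cluster was seen.

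T cells of C2D (103, against 183 in S2D) had cell cycle genes at least 2-fold higher in 7 of 21 (median 0.77) and interferon response genes in 6 of 13 (median 0.70), and Il22, a cytokine that acts on epithelia, stood at -6.58 (-11.89 to -4.08) from 1 UMI in C2D and 155 in S2D. Macrophage genes moved with them, with Lyz2 at 6.12 (5.66 to 6.62). NK cells of C2D (53, against 52) had cell cycle genes at least 2-fold higher in 8 of 11 (median 1.26) and dissociation genes at least 2-fold lower in 8 of 18 (median -0.76). In dendritic cells Ly6d, a marker shared with plasmacytoid cells, stood at 5.57 (3.71 to 8.62), and 23 of the 24 cells of the cluster led by Siglech, Ly6d and Cox6a2 came from C2D. At 6 weeks, T cells of C6W had Areg, an epidermal growth factor receptor ligand, at -3.94 (-4.69 to -3.27) and Ifng, interferon gamma, at -1.75 (-2.18 to -1.32), and B cells had Ighg2b at 2.24 (1.34 to 3.29), while against S2D these stood at -2.59, -1.15 and 0.97. Lyz2 moved at 6 weeks too, at 104.0 CPM in T cells of C6W and without a UMI in those of S6W.

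In ductal-like cells 8 genes were at least 2-fold higher at both times, where independence gave 0.730: Anxa1, Aqp5, C3, Cldn2, Cxcl2, Fabp5, Gem and Rgs5, named after their values were seen. C3 stood at 1.41 (1.003 to 1.85) and Fabp5 at 1.49 (0.94 to 2.10) at 6 weeks, but against S2D at 0.40 and 1.22, with Cxcl2 at -1.04. Also 2 were lower at both (0.255 if independent), 3 were higher at 2 days and lower at 6 weeks (0.174) and 5 the other way (1.07), so genes of opposite direction also exceeded independence. In macrophage-like cells 26 genes were higher at 2 days and lower at 6 weeks and 30 the other way, where independence gave 11.4 and 6.26, but 28 were lower at both and 10 higher at both, against 11.7 and 6.11.

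A hypothesis was that the ductal-like cells of C2D may hold cells of recent acinar origin that still carry digestive mRNA. They had a mean of 145.6 and a median of 36.0 digestive UMIs per cell. A first comparison, with T and B cells alone (mean 51.3, median 17.0), gave 2-fold to 3-fold higher values. Without the cells of over 500 such UMIs, 6 of 176 in ductal-like cells, the means were 48.1 and 23.5. The test was then widened to the highest of T or B cells, fibroblast-like and macrophage-like cells, which reached a mean of 116.2 and a median of 22.0. Both comparisons fell between the bounds set for and against, so acinar origin and free acinar RNA cannot be told apart.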
